A study of Dugesia japonica with 12 samples.

How the data were processed

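Polyadenylated RNA from whole worms was measured in 12 libraries, 3 from unexposed worms and 3 each after 1, 3 and 5 days in 64 mg per L glyphosate. Groups and replicate numbers were taken from the labels. Per the submitters' processing notes, cutadapt, FastQC, Salmon and edgeR were used; their versions and settings are not given in the sources used here. The deposited table holds values in TPM as far as the values show: the header does not name the unit, each library sums to 978610 to 986584, and Salmon reports TPM. All 30535 listed genes reach at least 2.01 TPM in some library, so the table appears to have been filtered on its highest value. Gene identifiers have the form of names from a transcript assembly, and the deposited table pairs them with annotation hits; 12425 genes have an annotation name and 9375 a Swiss-Prot hit. Lengths in the deposited table run from 201 to 8278 bases. The table has 0 per-sample columns beyond those of the 12 libraries.

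The tests were set before the data were examined for either counts or normalized values, and the branch for normalized values was used since the table holds no counts. TPM keeps no sequencing depth, so depth per library is unknown and no counting interval or detection limit is given. Genes with at least 1 TPM in at least 3 libraries were kept (27329). Values were taken as log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3, with an intensity trend, all 12 libraries in 1 fit of 4 groups and no fold minimum. Adjusted p-values are Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Comparisons were each exposure time with control, the exposure times with each other, and an F test over the 4 groups.

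Gene lists, 36 in all, were fixed before the data were examined as patterns on annotation text, covering stress, detoxification, cell death, proliferation, metabolism and signalling, planarian cell types, and other sources of RNA (vertebrate food tissue, bacteria, and protists, algae or fungi). They were tested with camera at a preset correlation of 0.01, adjusted over the 108 tests of 36 lists and 3 comparisons, and again with an estimated correlation and with fry. Members were counted past the gene-level threshold over all genes and adjusted over the list alone. The small heat shock transcripts were not caught by the heat shock pattern, because their annotation abbreviates the name. The spelling of 1 pattern of the repair list was changed after the data were seen, with the members of the list unchanged.

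Named genes followed a rule fixed before the data were examined. For each exposure time against control it took (a) the 6 largest rises and 6 largest falls among called genes whose groups do not overlap, whose mean over the 12 libraries is at least 5 TPM and whose annotation names a protein (not uncharacterized, hypothetical, predicted or unnamed), and (b) in each list the called members with the largest rise and fall and that mean. All of (a) are named, then (b) from the lists with the smallest p, up to 30 genes. The database tag PREDICTED before a protein name was not read as an exclusion, a gene counted as named where either its annotation hit or its Swiss-Prot hit names a protein, and names that are only a locus code were read as naming no protein. The last 2 readings were settled after the data were seen, and the first of them let in the metallothionein-like and NLRC3 transcripts, whose annotation hits are hypothetical proteins. Genes named outside the rule are stated as chosen after their values were seen. The values of 1 gene that the rule took at day 5 are not reported here.

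Classes of best hit were set after the data were seen: flatworm and bovid from the species of the annotation hit, ciliate and plant from the species of the Swiss-Prot hit, in that order of priority. Alternatives set beforehand were quantile normalization, no low-value filter, a filter of at least 5 TPM in at least 3 libraries, limma without an intensity trend, an absolute log2 fold change of at least 1, a replicate block, a pseudocount of 0.1, only the 6 libraries compared, and leaving out each library. Added after seeing the data were median-ratio scaling, rescaling without the 2 most abundant transcripts, only genes with flatworm hits, and leaving out both libraries with the highest medians (control replicate 1 and day 3 replicate 2).

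The procedure was tested on simulated values for 27329 genes with 200 genes changed at day 5, 100 of each size. Changed genes were drawn only from those with a mean log2(TPM + 1) of at least 2. Noise was independent between genes, without offsets of whole libraries. For day 5 against control, 36% of changes of 1 on the log2 scale and 93% of changes of 2 were called, and 11 unchanged genes were called. These shares do not cover lower genes or noise shared between genes. For day 1 against control, simulated with no change, 0 genes were called. No genome reference was used.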

Results

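Whole freshwater planarians of a clonal laboratory strain of Dugesia japonica, a free-living flatworm that regenerates from a stem cell population called neoblasts, were exposed to the herbicide glyphosate at 64 mg per L. Polyadenylated RNA was sequenced from unexposed worms and from worms after 1, 3 and 5 days of exposure, with 3 libraries in each of the 4 groups and 12 in all. The question was how the transcriptome of the worm changes with the length of exposure. The values were in TPM, transcript abundance scaled to a fixed total, for 30535 assembled genes, of which 27329 were tested. Each library summed to between 978610 and 986584 TPM, and between 18888 and 23602 genes reached 1 TPM. Sequencing depth is unknown because TPM keeps no depth. No genome coordinates go with assembled genes, so each gene is given by its assembly identifier and its best annotation hit. Group values are mean TPM ± SD with n = 3 libraries, and fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The labels give no sampling day for the unexposed worms.

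The best hits pointed to several organisms. Among tested genes, 4159 had a flatworm protein as best hit, 51 a bovid one (cattle, bison, buffalo, sheep, goat or antelope), 72 a ciliate one in Swiss-Prot and 659 a plant one in Swiss-Prot, while 15428 had no hit. A best hit is a similarity and not an identification of the organism that made the RNA. The most abundant transcript, TRINITY_DN37864_c2_g1 with 266 bases and no hit, held 37.9 ± 7.30% of the total in control and 30.004 ± 1.86% at day 5. The next, TRINITY_DN36963_c0_g5 with 231 bases and no hit, held 6.48 ± 4.83% in control, 4.74 ± 1.94% at day 1, 22.2 ± 6.53% at day 3 and 20.8 ± 3.55% at day 5. These shares enter every TPM value because all genes share a fixed total. Within groups, log2 values correlated across genes with Pearson's r of 0.914 to 0.942, where genes are not independent replicates.

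On the 500 most variable genes, control libraries lay between -24.2 and -14.7 on the first principal component, which held 41.2% of the variance. Day 1 libraries lay between -14.0 and -8.90, day 3 libraries between 8.38 and 19.7, and day 5 libraries between 14.5 and 19.3. With all tested genes the first component held 19.97%. In the test over all 4 groups, 502 genes differed (limma, adjusted p under 0.05). This count was 272 and 286 without control replicates 1 and 3, 332 without day 1 replicate 1, and 291, 328 and 318 without day 5 replicates 1, 2 and 3.

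**Figure D1:**
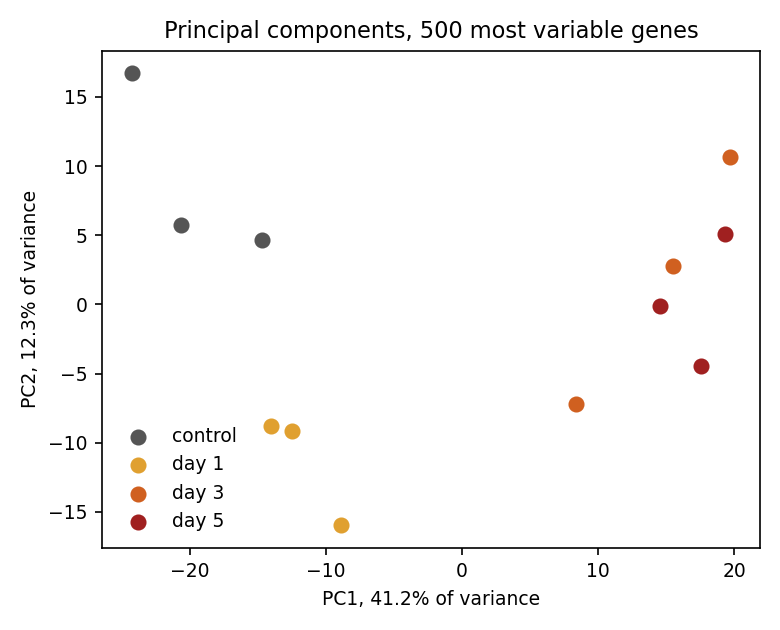
Positions of the 12 libraries on the first 2 principal components of log2(TPM + 1) for the 500 most variable genes; each point is a library and colours mark the group. Control libraries lie at or below -14.7 on the horizontal axis, and all day 3 and day 5 libraries at or above 8.38.

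After 1 day of exposure, 2 small heat shock transcripts, a cathepsin L and a lifeguard-like transcript were higher than in control. The heat shock list, whose pattern did not catch the small heat shock transcripts, had 0 rises and 1 fall among 114 by either adjustment (median -0.19, adjusted p = 0.217). The small heat shock protein transcripts of Dugesia japonica, chaperones that bind unfolding proteins, rose from 25.4 ± 5.15 to 121 ± 4.23 TPM for TRINITY_DN38028_c0_g1 (log2 fold change 2.23, SE 0.27, adjusted p = 0.00180) and from 41.4 ± 10.99 to 182 ± 11.3 TPM for TRINITY_DN38028_c0_g2 (log2 fold change 2.14, SE 0.26, adjusted p = 0.00180). Their identifiers place both in one assembly cluster, so reads may be split between them and each level is uncertain. The largest rise under the rule for named genes, which leaves out transcripts without a named hit, was that of a cathepsin L, a lysosomal cysteine protease, from 0.393 ± 0.0702 to 7.95 ± 1.54 TPM (TRINITY_DN2937_c0_g1, log2 fold change 2.67, SE 0.26, adjusted p = 0.000586); its Swiss-Prot hit is a ciliate protein. A lifeguard-like protein, of a family known to inhibit cell death, rose from 0.810 ± 0.629 to 5.88 ± 1.36 TPM (TRINITY_DN35442_c1_g1, log2 fold change 1.98, SE 0.30, adjusted p = 0.00925).

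Further named rises at day 1 concerned signalling and vesicle traffic. A TNF receptor-associated factor 3 transcript, an adaptor of immune signalling, went from 10.6 ± 0.920 to 33.3 ± 6.59 TPM (TRINITY_DN33177_c0_g2, adjusted p = 0.0443). An ADP-ribosylation factor with a plant hit, a small GTPase of vesicle traffic, went from 1.33 ± 0.378 to 5.88 ± 1.66 TPM (TRINITY_DN39308_c2_g1, adjusted p = 0.0269). Only 3 genes met the rule for named falls. A MAP kinase kinase kinase transcript fell from 10.9 ± 4.46 to 2.53 ± 1.07 TPM (TRINITY_DN38062_c1_g1, adjusted p = 0.0443). Alpha-tubulin transcripts fell from 44.0 ± 9.79 to 17.6 ± 1.65 TPM (TRINITY_DN33524_c1_g5, adjusted p = 0.0173) and from 52.7 ± 7.29 to 23.3 ± 1.17 TPM (TRINITY_DN35753_c5_g2, adjusted p = 0.0257). These 2 belong to a multigene family, so reads may be shared with near-identical copies. The first shares an assembly cluster with ciliate-hit alpha-tubulins TRINITY_DN33524_c1_g3 and TRINITY_DN33524_c1_g12, so its separate level and its organism are uncertain. The 6 largest rises and falls named at each time were taken only from genes whose control and exposed values do not overlap.

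As a group, 8 of 36 gene lists stood lower than other genes at day 1 and 0 stood higher (camera with a preset correlation, adjusted p under 0.05). None of these calls held with an estimated correlation (adjusted p = 0.999 for all lists). At day 1 the median log2 fold change was -0.13 for flatworm-hit genes and -0.13 for other genes with unclassified hits. It was -0.003 for the 15428 genes without a hit, so annotated lists lean lower against the full set of genes. Neoblast markers had a median log2 fold change of -0.38 over 55 tested members (adjusted p = 2.75e-05), with 0 members past the gene-level threshold over all genes and 1 fall adjusted over the list alone. Ribosomal proteins stood at -0.23 over 307 members and DNA replication and cell cycle genes at -0.31 over 93, with 0 members called in either, also adjusted over the list alone. The DNA repair list stood at -0.32 over 41 members with 0 called, also adjusted over the list alone. The apoptosis list (median -0.17, 1 of 173 called, TNF receptor-associated factor 3, which rose, and 1 rise and 1 fall adjusted over the list alone) and the cilia list (median -0.21, 0 of 132 called by either adjustment) were also lower. So were the reactive oxygen and MAPK list (median -0.20, 1 of 173 called, the kinase named above, also adjusted over the list alone) and ABC transporters (median -0.26, 0 of 26 called, 1 fall adjusted over the list alone). Among members with a flatworm hit, the neoblast (adjusted p = 4.77e-05), replication (adjusted p = 0.00132) and ribosomal lists (adjusted p = 0.0235) stood lower than other flatworm-hit genes, while the apoptosis (adjusted p = 0.733), repair (adjusted p = 0.250), cilia (adjusted p = 0.331) and reactive oxygen lists (adjusted p = 0.591) did not pass there. Oxidative phosphorylation genes with flatworm hits stood higher than other flatworm-hit genes at day 1 (adjusted p = 0.0102), with 0 called. Their median was 0.02, near control, against -0.13 for all flatworm-hit genes. No list test among flatworm-hit genes, at any of the 3 times, held with an estimated correlation (adjusted p = 0.998).

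Several of these list calls hung on single libraries. Leaving out control replicate 1 ended those of the ABC transporter (adjusted p = 0.148), apoptosis (adjusted p = 0.0528), repair (adjusted p = 0.0744), cilia (adjusted p = 0.225) and reactive oxygen lists (adjusted p = 0.194). Leaving out day 1 replicate 3 ended those of the ABC transporter (adjusted p = 0.177), apoptosis (adjusted p = 0.106), cilia (adjusted p = 0.0976) and reactive oxygen lists (adjusted p = 0.0976). The ABC transporter call was also lost without control replicate 3 (adjusted p = 0.160), day 1 replicate 1 (adjusted p = 0.0575), day 3 replicates 1 and 3 (adjusted p = 0.0538 and 0.0613), and day 5 replicates 1, 2 and 3 (adjusted p = 0.0559, 0.0724 and 0.0642). With only genes of at least 5 TPM in 3 libraries, the same 5 lists gave adjusted p from 0.0555 to 0.181, and quantile normalization gave 0.0508 for apoptosis. In all 28 list calls of the 3 times the median, the mean and the test had the same sign.

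In all, 36 genes passed adjusted p under 0.05 at day 1 against control (limma with an intensity trend), 23 higher and 13 lower, of which 3 higher and 0 lower had a flatworm hit. After quantile normalization 51 were higher and 23 lower, after median-ratio scaling 64 and 24, and after rescaling without the 2 most abundant transcripts 23 and 19. The majority turned in limma without an intensity trend, with 17 higher and 21 lower, while a pseudocount of 0.1 gave 32 and 5. The count depended on single libraries, being 16 without control replicate 1, 92 without control replicate 2, 22 without control replicate 3, and 16, 15 and 23 without day 1 replicates 1, 2 and 3. It was 57 without day 3 replicate 2 and 21 without day 5 replicate 3, which enter through the shared spread. The cathepsin L and both small heat shock transcripts kept their calls under all 22 alternatives, while the other 6 named genes each lost the call under 4 (lifeguard-like) to 13 (MAP kinase kinase kinase) of them, with highest adjusted p-values of 0.102 to 0.225.

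After 3 days small heat shock, E1-like and metallothionein-like transcripts were higher than in control, and ciliate-hit histone transcripts were lower. Small heat shock protein transcripts reached 234 ± 111 TPM (TRINITY_DN38028_c0_g1, log2 fold change 3.07, SE 0.27, adjusted p = 1.80e-05) and 286 ± 125 TPM (TRINITY_DN38028_c0_g2, log2 fold change 2.70, SE 0.26, adjusted p = 5.17e-05). A transcript of only 234 bases named as an E1-like ubiquitin-activating enzyme, which starts ubiquitin conjugation, rose from 10.3 ± 5.00 to 70.1 ± 13.0 TPM (TRINITY_DN34907_c1_g2, log2 fold change 2.75, SE 0.29, adjusted p = 9.47e-05). Its Swiss-Prot hit is a fission yeast protein. The largest rise under the rule for named genes was that of a type 3 metallothionein-like transcript with a plant hit, a small metal-binding protein, from 0.360 ± 0.180 to 11.6 ± 2.31 TPM (TRINITY_DN23386_c0_g2, log2 fold change 3.20, SE 0.24, adjusted p = 3.42e-06). Cathepsin L TRINITY_DN2937_c0_g1 stood at 7.09 ± 2.82 TPM (adjusted p = 8.71e-05) and an actin with a ciliate hit rose from 4.70 ± 0.617 to 27.3 ± 18.6 TPM (TRINITY_DN21497_c0_g2, adjusted p = 0.0103).

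All 6 of the largest falls under the rule at day 3 were histone or centrin transcripts, and 5 of them had ciliate hits. Histones package DNA, and centrin is a calcium-binding protein of basal bodies. Histone H3 fell from 23.7 ± 1.26 to 0.493 ± 0.253 TPM (TRINITY_DN38360_c2_g2, log2 fold change -4.06, SE 0.31, adjusted p = 3.44e-06), and an H3.v1-like transcript from 27.6 ± 4.34 to 1.03 ± 0.617 TPM (TRINITY_DN40634_c0_g1, log2 fold change -3.85, SE 0.27, adjusted p = 2.61e-06). Histone H2B fell from 40.2 ± 4.21 to 2.11 ± 0.635 TPM (TRINITY_DN40711_c0_g1, adjusted p = 5.68e-05). A pair of histone H4-like transcripts fell from 23.03 ± 3.999 to 1.42 ± 0.770 TPM (TRINITY_DN32064_c2_g4, adjusted p = 6.42e-06) and from 23.7 ± 3.13 to 2.51 ± 0.454 TPM (TRINITY_DN32064_c2_g6, adjusted p = 5.82e-05). They share an assembly cluster, so their separate levels are uncertain. Centrin-2 fell from 65.1 ± 21.9 to 9.24 ± 11.4 TPM (TRINITY_DN16790_c0_g1, adjusted p = 0.00683).

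Proliferation genes were lower at day 3 by list tests that did not hold with an estimated correlation (adjusted p = 0.999 for both lists). Of 55 tested neoblast markers, 9 fell and 0 rose (list median -0.30, adjusted p = 0.000440), with 10 falls adjusted over the list alone. Of the 9, 7 had flatworm hits. The small subunit of ribonucleotide reductase, which makes DNA precursors, fell from 24.0 ± 4.62 to 7.06 ± 1.66 TPM (TRINITY_DN33815_c0_g1, log2 fold change -1.64, SE 0.21, adjusted p = 0.000731). Others, chosen after their values were seen, were proliferating cell nuclear antigen, the DNA polymerase clamp, at 15.2 ± 0.929 and 7.997 ± 0.884 TPM (TRINITY_DN29941_c0_g1, adjusted p = 0.0394), and the planarian VASA-like gene DjVLGA at 61.8 ± 9.80 and 28.5 ± 2.84 TPM (TRINITY_DN35646_c1_g2, adjusted p = 0.0101). The DNA replication and cell cycle list, which shares 20 members with the neoblast list, had 5 falls and 1 rise among 93, and 6 and 1 adjusted over the list alone (median -0.19, adjusted p = 0.0404). Its riser was an unc-51-like kinase transcript, from 9.17 ± 1.98 to 26.03 ± 4.94 TPM (TRINITY_DN35609_c0_g1, adjusted p = 0.0116), whose Swiss-Prot hit is the yeast cell division kinase CDC15. Unc-51-like kinases are known to start autophagy. The replication list also lost its call without control replicate 1 (adjusted p = 0.294) or 3 (adjusted p = 0.0784), day 1 replicate 1 (adjusted p = 0.0506) or 3 (adjusted p = 0.0607), day 3 replicate 1 (adjusted p = 0.234) or 3 (adjusted p = 0.122), or day 5 replicate 3 (adjusted p = 0.0516), and after rescaling without the 2 most abundant transcripts (adjusted p = 0.0570).

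Ribosomal proteins and oxidative phosphorylation genes were lower as groups at day 3, and gut markers higher. None of these 3 list calls held with an estimated correlation (adjusted p = 0.999). Of 307 ribosomal proteins 14 fell and 0 rose (46 falls and 4 rises adjusted over the list alone), with a list median of -0.36 (adjusted p = 4.17e-07). Of the members, 37 had ciliate hits. Among the 40 members with flatworm hits the median was -0.58 with 5 falls (adjusted p = 2.19e-12 against other flatworm-hit genes). Ribosomal protein S5 of the small subunit fell from 13.4 ± 3.45 to 6.03 ± 1.14 TPM (TRINITY_DN28695_c0_g1, adjusted p = 0.0345). Of 124 oxidative phosphorylation genes 5 fell, all with flatworm hits (median -0.19, adjusted p = 0.00104; 5 falls adjusted over the list alone). The mitochondrially encoded NADH dehydrogenase subunit ND3, a part of respiratory complex I, fell from 112 ± 43.1 to 23.4 ± 7.25 TPM (TRINITY_DN34363_c3_g9, log2 fold change -2.18, SE 0.28, adjusted p = 0.000598). Gut markers stood higher (median 0.11 over 194, 2 rises and 1 fall, the same numbers adjusted over the list alone, adjusted p = 0.00238), and among the 44 with flatworm hits the median was 0.29 with 0 called (adjusted p = 0.000101). The called members of the full list were 2 cathepsin L transcripts without flatworm hits, and the faller was a bovid-hit apolipoprotein A-II. The oxidative phosphorylation call was lost without day 3 replicate 2 (adjusted p = 0.110).

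Autophagy genes (median 0.17 over 27, 1 rise, adjusted p = 0.0155; 3 rises adjusted over the list alone) and patterning genes of the Wnt, BMP and hedgehog pathways (median 0.15 over 45, 0 called, adjusted p = 0.0255) stood higher at day 3. The vertebrate tissue list (median -0.67 over 47, 2 falls, adjusted p = 2.05e-07; 12 falls adjusted over the list alone) and the bacterial and shikimate pathway list (median -0.36 over 15, 2 falls, adjusted p = 0.0190; 5 adjusted over the list alone) stood lower. The estimated correlation ended all 4 calls (adjusted p = 0.999). The 2 falls of the bacterial list were transcripts annotated as resembling bacterial ribosomal RNA. Without day 3 replicate 2 the patterning list gave adjusted p = 0.434 and the bacterial list adjusted p = 0.239, and without control replicate 2 the patterning list gave adjusted p = 0.184. The stricter filter ended the calls of the vertebrate (adjusted p = 0.0820) and bacterial lists (adjusted p = 0.752), quantile normalization that of the bacterial list (adjusted p = 0.0508), and flatworm hits alone that of autophagy (adjusted p = 0.421).

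Single members of other lists changed at day 3 without a list call. A catalase, which removes hydrogen peroxide, rose from 20.8 ± 8.01 to 58.7 ± 23.5 TPM (TRINITY_DN32940_c1_g1, adjusted p = 0.0321). A transcript named HSP70, a chaperone, with the constitutive heat shock cognate protein as Swiss-Prot hit, rose from 16.3 ± 4.64 to 63.2 ± 43.6 TPM (TRINITY_DN39397_c1_g1, adjusted p = 0.0328), and TNF receptor-associated factor 3 stood at 38.6 ± 20.4 TPM (TRINITY_DN33177_c0_g2, adjusted p = 0.00675). Ferritin heavy chain, an iron store, fell from 90.7 ± 10.3 to 38.7 ± 8.50 TPM (TRINITY_DN35717_c1_g2, adjusted p = 0.00867). A transcript named glutathione S-transferase, an enzyme that conjugates foreign compounds, with a prostaglandin D synthase hit in Swiss-Prot, fell from 221 ± 31.0 to 117 ± 25.2 TPM (TRINITY_DN29717_c0_g1, adjusted p = 0.0206). Pyruvate kinase, the last enzyme of glycolysis, fell from 66.1 ± 15.3 to 31.6 ± 7.45 TPM (TRINITY_DN37807_c1_g2, adjusted p = 0.0246), and a beta carbonic anhydrase from 13.8 ± 1.92 to 7.06 ± 0.372 TPM (TRINITY_DN33952_c1_g2, adjusted p = 0.0439). Phosphoserine phosphatase, of serine synthesis, fell from 11.4 ± 2.05 to 5.43 ± 0.569 TPM (TRINITY_DN33425_c1_g1, adjusted p = 0.0328). A proteasome alpha subunit fell from 112 ± 10.5 to 59.9 ± 8.40 TPM (TRINITY_DN34971_c0_g1, adjusted p = 0.0185). Further falls were a planarian TRAF2-like transcript (TRINITY_DN37959_c0_g1, log2 fold change -1.21), an interferon-inducible 27-like transcript (TRINITY_DN39431_c2_g1, log2 fold change -1.24), a transcript named for HSP70 family member 12A whose Swiss-Prot hit is a TFIID subunit (TRINITY_DN34254_c1_g7, log2 fold change -1.06), and a DIM1 family spliceosome protein that the antioxidant list took by its thioredoxin-like name (TRINITY_DN14613_c0_g1, log2 fold change -0.87).

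At day 3, 442 genes passed adjusted p under 0.05 against control (limma), 117 higher and 325 lower, of which 9 higher and 62 lower had flatworm hits. The split depended on scaling, being 427 higher and 442 lower after quantile normalization, 350 and 417 after median-ratio scaling and 193 higher and 210 lower after rescaling without the 2 most abundant transcripts, and the count was 187 without control replicate 1, 229 without control replicate 3 and 230 without day 3 replicate 3. Of 29 named genes 14 kept their calls under all 22 alternatives, and the others lost them under some, with highest adjusted p-values of 0.0561 to 0.229. The numbers of alternatives that ended a call were 19 for the DIM1 family protein, 15 each for the carbonic anhydrase and phosphoserine phosphatase, 10 for S5, 9 for the interferon-inducible transcript, 7 each for catalase, HSP70, the proteasome subunit and pyruvate kinase, and 5 for the glutathione S-transferase. They were 2 each for the unc-51-like, TRAF2-like and HSP70 12A transcripts and 1 each for actin and ferritin.

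**Figure D2:**
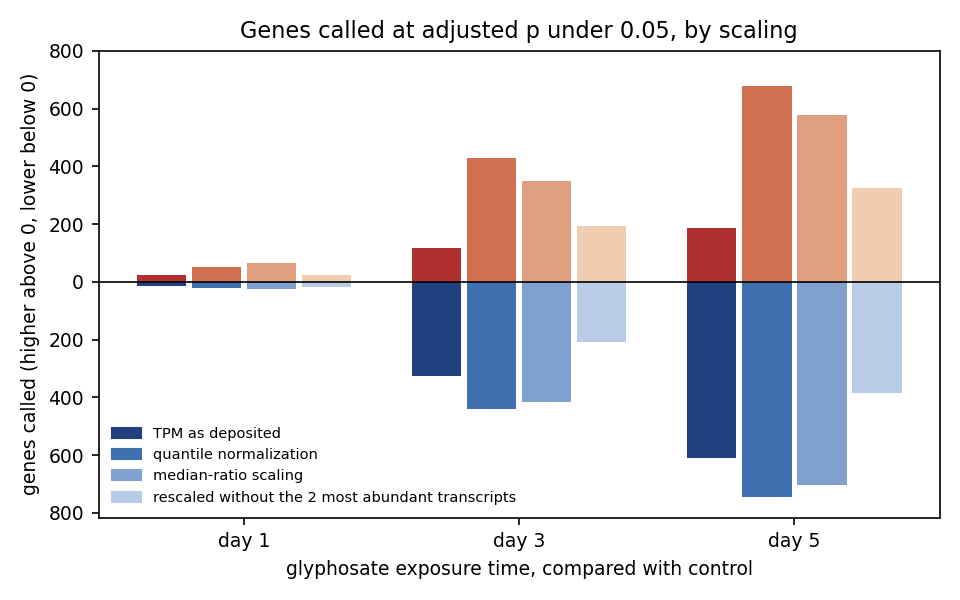
Genes past adjusted p under 0.05 (limma) at each exposure time against control, higher above 0 in red shades and lower below 0 in blue shades; in each group of bars the scaling runs in the order of the key. With the TPM values as deposited, 186 genes were higher and 609 lower at day 5, against 679 and 746 after quantile normalization.

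After 5 days small heat shock and E1-like transcripts were higher than in control, and ciliate-hit histones lower. Small heat shock protein transcripts stood at 198 ± 42.8 TPM (TRINITY_DN38028_c0_g1, log2 fold change 2.91, SE 0.27, adjusted p = 2.15e-05) and 262 ± 33.7 TPM (TRINITY_DN38028_c0_g2, log2 fold change 2.65, SE 0.26, adjusted p = 4.05e-05). The E1-like enzyme stood at 64.9 ± 5.95 TPM (TRINITY_DN34907_c1_g2, log2 fold change 2.65, SE 0.29, adjusted p = 0.000110) and the metallothionein-like transcript at 10.98 ± 1.13 TPM (TRINITY_DN23386_c0_g2, log2 fold change 3.14, SE 0.24, adjusted p = 3.38e-06). Cathepsin L stood at 6.37 ± 0.263 TPM (TRINITY_DN2937_c0_g1, adjusted p = 9.96e-05) and the lifeguard-like transcript at 8.02 ± 0.728 TPM (TRINITY_DN35442_c1_g1, adjusted p = 0.000313). All of these kept their calls under all 22 alternatives.

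**Figure D3:**
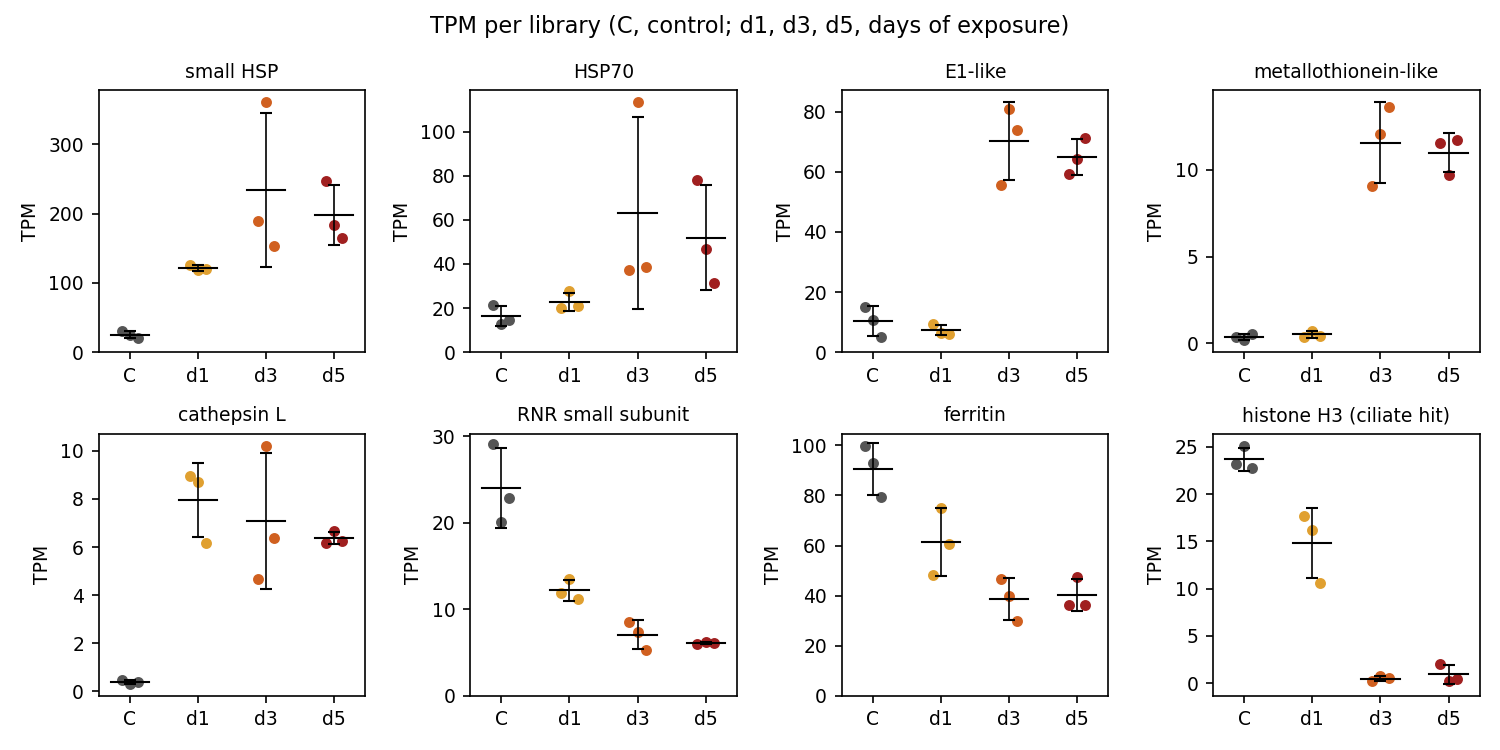
TPM of 8 named genes in each library, by group; points are libraries, horizontal lines group means and bars ± 1 SD (n = 3). Small heat shock protein and cathepsin L are higher from day 1, the E1-like and metallothionein-like transcripts are near control at day 1 and higher at days 3 and 5, and histone H3 is below 3 TPM in all libraries of days 3 and 5.

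Histone transcripts with large falls at day 5 were histone H2B, from 40.2 ± 4.21 to 1.85 ± 1.79 TPM (TRINITY_DN40711_c0_g1, log2 fold change -4.04, SE 0.37, adjusted p = 2.15e-05), the H3.v1-like transcript, to 0.763 ± 0.404 TPM (TRINITY_DN40634_c0_g1, adjusted p = 1.98e-06), and histone H3, to 0.937 ± 0.998 TPM (TRINITY_DN38360_c2_g2, adjusted p = 5.62e-06). Centrin-2 fell to 3.73 ± 0.835 TPM (TRINITY_DN16790_c0_g1, adjusted p = 0.00185), and a caltractin, another centrin with a ciliate hit, from 17.95 ± 2.36 to 0.570 ± 0.419 TPM (TRINITY_DN39555_c1_g10, adjusted p = 4.38e-06). A bovid-hit transcript listed as NLRC3 fell from 181 ± 190.4 to 7.36 ± 4.37 TPM (TRINITY_DN32560_c2_g4, log2 fold change -4.02, SE 0.78, adjusted p = 0.0114), a change lost without control replicate 1 or day 5 replicate 1 (highest adjusted p = 0.0623).

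Proliferation and repair genes were lower at day 5 by list tests. The 3 calls were lost with an estimated correlation (adjusted p = 0.999). Of 55 neoblast markers 9 fell and 0 rose, and 20 fell adjusted over the list alone (median -0.50, adjusted p = 7.45e-07); among the 39 with flatworm hits 7 fell, with a median of -0.64 (adjusted p = 8.71e-07). The ribonucleotide reductase small subunit stood at 6.09 ± 0.107 TPM (TRINITY_DN33815_c0_g1, log2 fold change -1.80, SE 0.21, adjusted p = 0.000217). Minichromosome maintenance protein MCM4, a part of the replicative helicase chosen after its values were seen, fell from 12.4 ± 2.78 to 4.95 ± 0.320 TPM (TRINITY_DN34681_c0_g1, adjusted p = 0.0110). Of 93 replication and cell cycle genes 6 fell and 0 rose, with 13 falls and 2 rises adjusted over the list alone (median -0.41, adjusted p = 0.000440). In the DNA repair list 1 of 41 fell and 0 were called adjusted over the list alone (median -0.36, adjusted p = 0.0190). The repair call was also lost without control replicate 1 (adjusted p = 0.114) or 3 (adjusted p = 0.0526) or day 5 replicate 3 (adjusted p = 0.113), with the stricter filter (adjusted p = 0.0621), and with flatworm hits alone (adjusted p = 0.172).

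Translation and energy gene lists stood lower at day 5, with 3 calls that an estimated correlation ended (adjusted p = 0.999). Of 307 ribosomal proteins 40 fell and 1 rose, and 102 fell adjusted over the list alone (median -0.44, adjusted p = 3.64e-09). Among the 40 with flatworm hits 9 fell (median -0.57, adjusted p = 4.55e-10). The largest faller above 5 TPM was L29 of the large subunit with a ciliate hit, from 11.2 ± 1.52 to 1.45 ± 0.615 TPM (TRINITY_DN18703_c0_g1, adjusted p = 0.00421), and the riser was S12 with a plant hit, from 74.4 ± 9.47 to 129 ± 14.2 TPM (TRINITY_DN26206_c0_g1, adjusted p = 0.0234). Of 124 oxidative phosphorylation genes 12 fell and 0 rose, and 21 fell adjusted over the list alone (median -0.23, adjusted p = 0.000474). Of the 12, 7 were bovid-hit mitochondrial transcripts and 4 had flatworm hits. The bovid-hit ND3 fell from 91.1 ± 11.7 to 17.7 ± 19.97 TPM (TRINITY_DN41703_c0_g1, adjusted p = 0.0188), and the flatworm-hit ND3, chosen at day 5 after its values were seen, stood at 24.8 ± 3.93 TPM (TRINITY_DN34363_c3_g9, adjusted p = 0.000678). Of 44 citric acid cycle genes 2 fell (median -0.24, adjusted p = 0.0310; 5 falls adjusted over the list alone), of which TRINITY_DN37477_c0_g1, with a fumarate hydratase hit in Swiss-Prot and another name in its other hit, went from 81.0 ± 16.1 to 44.4 ± 9.91 TPM. The citric acid cycle call was lost without control replicate 1 (adjusted p = 0.0688), control replicate 2 (adjusted p = 0.122) or day 5 replicate 1 (adjusted p = 0.0958). It was lost as well with the stricter filter (adjusted p = 0.0867), flatworm hits alone (adjusted p = 0.0768), quantile normalization (adjusted p = 0.0858) and rescaling without the 2 most abundant transcripts (adjusted p = 0.0977).

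Gut, phagocyte and autophagy lists stood higher at day 5. None of the 3 calls held with an estimated correlation (adjusted p = 0.999). Of 194 gut markers 7 rose and 2 fell (median 0.17, adjusted p = 0.000406; 10 rises and 5 falls adjusted over the list alone), and among the 44 with flatworm hits 2 rose (median 0.36, adjusted p = 8.71e-07). Cathepsin transcripts chosen after their values were seen were a cathepsin B, from 29.0 ± 6.02 to 61.7 ± 5.83 TPM (TRINITY_DN39563_c3_g9, adjusted p = 0.0309), and a cathepsin L1-like transcript, from 294 ± 130.0 to 629 ± 76.1 TPM (TRINITY_DN34166_c8_g1, adjusted p = 0.0437). The largest gut faller above 5 TPM was an Xaa-Pro aminopeptidase, from 17.98 ± 2.51 to 9.69 ± 1.14 TPM (TRINITY_DN39341_c1_g1, adjusted p = 0.0360). Markers of cathepsin-positive phagocytes, 24 of which are also gut markers, had 5 rises and 3 falls among 77 (median 0.20, adjusted p = 0.00496; 11 rises and 6 falls adjusted over the list alone). Ferritin, one of the fallers, stood at 40.1 ± 6.41 TPM (TRINITY_DN35717_c1_g2, adjusted p = 0.00911). Autophagy genes had 1 rise among 27 (median 0.13, adjusted p = 0.00942; 4 rises adjusted over the list alone), an ATG8-like transcript with a plant hit, from 3.17 ± 0.911 to 9.10 ± 3.66 TPM (TRINITY_DN12706_c0_g1, adjusted p = 0.0460). The phagocyte call was lost without control replicate 1 (adjusted p = 0.0808) and with flatworm hits alone (adjusted p = 0.284), as was the autophagy call with flatworm hits alone (adjusted p = 0.206).

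The 15 transcripts with names that refer to ribosomal RNA, or to the ART2 and TAR1 proteins read from its genes, held 1.94 ± 1.23% of the total in control, 2.51 ± 0.440% at day 1, 1.39 ± 1.02% at day 3 and 1.27 ± 0.829% at day 5, and bovid-hit transcripts 2.28 ± 1.30%, 2.99 ± 0.389%, 1.75 ± 1.21% and 1.60 ± 0.906%. The 2 shares, of which the second lay mostly in 1 transcript and 1 transcript counts in both, correlated at r = 0.994 over the 12 libraries. Of the 3 lists for other sources of RNA, the vertebrate tissue and bacterial lists were lower at day 5, calls lost with an estimated correlation (adjusted p = 0.999). Of 47 genes in the vertebrate tissue list 11 fell, all with bovid hits, and 22 fell adjusted over the list alone (median -0.82, adjusted p = 5.39e-11). Among the fallers, chosen after their values were seen, were apolipoprotein A-II, a plasma lipoprotein, from 3.35 ± 0.523 to 0.0600 ± 0.0520 TPM (TRINITY_DN40762_c0_g1, adjusted p = 0.00221), and mitochondrial COX3, from 79.5 ± 14.1 to 16.5 ± 16.7 TPM (TRINITY_DN34317_c6_g1, adjusted p = 0.0123). Of 15 members of the bacterial and shikimate list 3 fell (median -0.45, adjusted p = 0.0190; 3 adjusted over the list alone), including a ribosomal protein S27 transcript, from 9.48 ± 0.861 to 3.06 ± 0.784 TPM (TRINITY_DN33207_c6_g1, adjusted p = 0.00450), whose Swiss-Prot hit is an archaeal ribosomal protein. The bacterial call was lost with the stricter filter (adjusted p = 0.748) and quantile normalization (adjusted p = 0.0522).

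Further named members changed at day 5 in lists that were not called. Collagen alpha chain transcripts, which planarian muscle expresses, fell, with TRINITY_DN37330_c0_g3 going from 148 ± 31.7 to 70.01 ± 20.5 TPM (adjusted p = 0.0233). It shares an assembly cluster with collagen TRINITY_DN37330_c0_g1, at 125 ± 26.01 and 63.2 ± 17.1 TPM (adjusted p = 0.0328), so their separate levels are uncertain, and this second collagen was chosen after its values were seen. Pyruvate kinase stood at 25.3 ± 3.06 TPM (TRINITY_DN37807_c1_g2, adjusted p = 0.00362), phosphoserine phosphatase at 5.18 ± 0.588 TPM (TRINITY_DN33425_c1_g1, adjusted p = 0.0174) and the beta carbonic anhydrase at 6.56 ± 0.202 TPM (TRINITY_DN33952_c1_g2, adjusted p = 0.0191). Outer dense fiber protein 3, a protein of motile cilia, fell from 46.5 ± 10.4 to 24.8 ± 2.85 TPM (TRINITY_DN32500_c0_g5, adjusted p = 0.0424). A planarian bcl2-like transcript, of the family that controls apoptosis, fell from 11.9 ± 2.74 to 5.197 ± 1.81 TPM (TRINITY_DN39481_c2_g9, adjusted p = 0.0496). TNF receptor-associated factor 3 stood at 24.8 ± 4.55 TPM (TRINITY_DN33177_c0_g2, adjusted p = 0.0418), and the small GTPase Rap-1b rose from 69.3 ± 16.2 to 127 ± 2.83 TPM (TRINITY_DN36667_c5_g2, adjusted p = 0.0385).

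**Figure D4:**
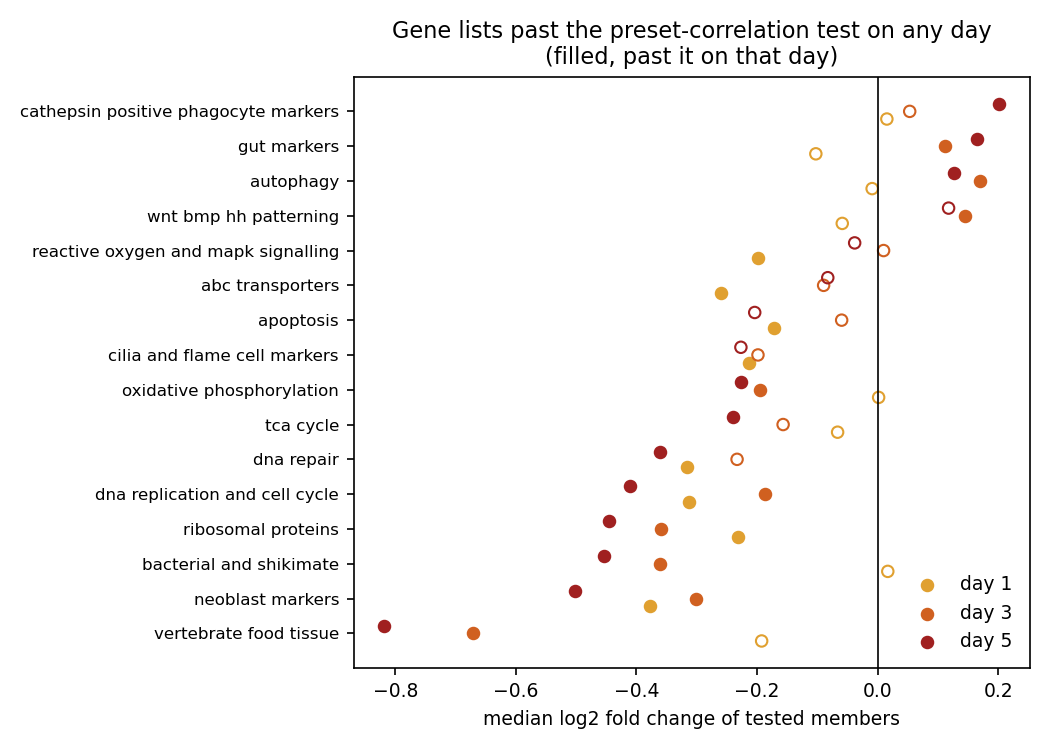
Median log2 fold change against control of the tested members of each gene list that passed the preset-correlation camera test on at least 1 day, for days 1, 3 and 5. Filled points passed adjusted p under 0.05 on that day; none did with an estimated correlation, and the vertebrate tissue list lies lowest, at -0.82 on day 5.

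At day 5, 795 genes passed adjusted p under 0.05 against control (limma), 186 higher and 609 lower, of which 16 higher and 122 lower had flatworm hits. The split depended on scaling, being 679 higher and 746 lower after quantile normalization, 577 and 702 after median-ratio scaling and 326 and 384 after rescaling without the 2 most abundant transcripts, and these moved the median gene from -0.09 to 0.01, 0.01 and 0.03. The count was 299 without control replicate 1, 522 without control replicate 3, and 275, 411 and 344 without day 5 replicates 1, 2 and 3. Of 30 named genes 15 kept their calls under all 22 alternatives, and the highest adjusted p-values of the others were 0.0503 to 0.213. Calls ended under 17 alternatives for the bcl2-like transcript, 12 for outer dense fiber protein 3, 11 each for the ATG8-like, fumarate hydratase and aminopeptidase transcripts, 9 for Rap-1b and 8 for TNF receptor-associated factor 3. S12, collagen and bovid-hit ND3 lost theirs under 7 each, the carbonic anhydrase under 5, phosphoserine phosphatase under 4, the NLRC3 transcript under 2 and ferritin under 1.

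Between exposure times, day 3 differed from day 1 in 49 genes, 12 higher and 37 lower, and day 5 from day 1 in 134, 27 higher and 107 lower (limma, adjusted p under 0.05). The split depended on scaling. For day 5 against day 1 it was 86 higher and 101 lower after quantile normalization and 56 and 104 after median-ratio scaling. Rescaling without the 2 most abundant transcripts gave 59 higher and 64 lower. Between day 5 and day 3, 0 genes passed. At an unadjusted p under 0.05 there were 842 of 27329 genes (limma), a smaller share than the 0.05 that unchanged genes would give on average. The metallothionein-like transcript TRINITY_DN23386_c0_g2 was higher at day 5 than at day 1 by a log2 fold change of 2.99 (adjusted p = 1.86e-05), and the E1-like transcript TRINITY_DN34907_c1_g2 by 3.01 (adjusted p = 8.43e-05). Ciliate-hit histone H3 TRINITY_DN38360_c2_g2 differed by -3.12 (adjusted p = 0.000115). The small heat shock transcripts, cathepsin L TRINITY_DN2937_c0_g1 and the ribonucleotide reductase transcript did not pass the threshold between exposure times. The count for day 3 against day 1 was 78 without day 3 replicate 1. That for day 5 against day 1 was 57, 66 and 67 without day 1 replicates 1, 2 and 3, and 50, 77 and 54 without day 5 replicates 1, 2 and 3.

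Calls overlapped between times. Of the genes called at day 1, 20 higher and 12 lower were called in the same direction at day 3, and 20 and 12 at day 5, while days 3 and 5 shared 80 higher and 279 lower and no pair had genes called in opposite directions. Independent lists of these sizes would share 0.796 higher and 7.24 lower between days 3 and 5. For day 1 the numbers were 0.0985 and 0.155 with day 3 and 0.157 and 0.290 with day 5. In simulations with all 12 libraries unchanged, controls included, shared calls averaged 0 for days 3 and 5. They averaged 0.05 for days 1 and 3 and 0 for days 1 and 5. Unchanged groups give almost no calls, so these simulated counts were low in advance and set no benchmark for the overlap. Fold changes at days 3 and 5 correlated across genes at r = 0.783, against 0.501 in the simulations, and their covariance was 0.232 against 0.0698. For days 1 and 3 the correlation was 0.569 against 0.500 and the covariance 0.140 against 0.0697, and for days 1 and 5 these were 0.565 against 0.500 and 0.145 against 0.0697. With 3 control libraries the controls could not be split into parts of 2 or more, so part of each excess may come from the shared controls. The simulations drew genes independently and without offsets of whole libraries, which ran from -0.237 to 0.361 in the real values. They therefore do not show how much such offsets add to the correlation and covariance.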

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

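All tests of explanations in this part were chosen after the results were seen; the comparisons between exposure times were planned. Effects against control differed between exposure times, by the direct test, in 49 genes for day 3 against day 1 and in 134 for day 5 against day 1. Because 3 libraries against 3 allow only 10 splits, no share under 0.05 can be reached for these. The real counts and the highest of the other splits were 36 and 1 for day 1 against control, 442 and 0 for day 3, 795 and 1 for day 5, 49 and 1 for day 3 against day 1, and 134 and 1 for day 5 against day 1. For day 5 against day 3 the real count was 0 and the highest other 3. For the 4 groups together, 1 of 100 splits, the real one, gave 502 genes and the highest other 235. Random relabelling of these libraries thus did not reach the real count. It cannot test differences between cultures, since the libraries of a group may be technical.

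Named genes that differed between exposure times are given as log2 fold changes. The metallothionein-like TRINITY_DN23386_c0_g2 differed by 3.04 at day 3 and 2.99 at day 5 from day 1, and the E1-like TRINITY_DN34907_c1_g2 by 3.11 and 3.01. Histone H3 TRINITY_DN38360_c2_g2 differed by -3.39 and -3.12, the H3.v1-like TRINITY_DN40634_c0_g1 by -2.65 and -2.83, and histone H2B TRINITY_DN40711_c0_g1 by -2.60 and -2.90. Histone H4-like TRINITY_DN32064_c2_g4 differed by -2.40 and -2.63, TRINITY_DN32064_c2_g6 by -1.54 and -1.70, and flatworm-hit ND3 TRINITY_DN34363_c3_g9 by -1.85 and -1.73. At day 5 against day 1 only, the test also passed for the bovid-hit TRINITY_DN32560_c2_g4 (-4.53), caltractin TRINITY_DN39555_c1_g10 (-2.19), ribosomal S12 TRINITY_DN26206_c0_g1 (0.90), bovid-hit ND3 TRINITY_DN41703_c0_g1 (-3.22) and collagen TRINITY_DN37330_c0_g3 (-1.29).

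Bovid-hit transcripts were lower at days 3 and 5, with a class median log2 fold change of -0.99 and -1.15 over 51 genes, 4 and 16 called lower and 0 higher, against -0.05 at day 1, and the camera test of the class passed at a preset correlation but not with an estimated one (adjusted p = 0.169 at both times). Scaling within libraries cannot account for this, since the class median relative to the flatworm-hit median of the same library moved by -0.69 between control and day 5, with an SD between libraries of 0.161. RNA of bovid tissue, such as food in the gut, may be the source, but the mean correlation of deviations from group means among the 18 class genes of at least 2 TPM was 0.201, against a 95th percentile of 0.202 for matched flatworm-hit sets, which leaves it open, and the class median relative to flatworm-hit genes moved with the share of transcripts named for ribosomal RNA (r = 0.698 over 12 libraries, 0.759 within groups). Mitochondrial COX1 TRINITY_DN37867_c0_g10, chosen after its values were seen, went from 235 ± 18.2 to 51.6 ± 53.1 TPM by day 5, unevenly between libraries. The most abundant member, skin secretory protein xP2-like TRINITY_DN39386_c2_g1, at 20586 ± 11501 and 15608 ± 9171 TPM, was not called (limma, adjusted p = 0.778). Glyphosate exposure and time since feeding cannot be told apart, because 0 unexposed libraries are placed by the labels at day 3 or day 5.

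Ciliate-hit transcripts were lower too, with class medians of -0.58, -0.88 and -1.28 at days 1, 3 and 5 and 31 of 72 called lower and 3 higher at day 5, though the camera test of the class passed at a preset correlation (adjusted p = 4.05e-07 at day 1) but not with an estimated one (adjusted p = 0.902, 0.490 and 0.355). Scaling cannot account for the falls, since the class median relative to flatworm-hit genes moved by -1.27 with an SD of 0.180. Fewer ciliates in the samples may account for the falls. The mean correlation of deviations was 0.404 among the 56 class genes of at least 2 TPM, above the 95th percentile of 0.0324 in matched sets. This cannot tell fewer ciliates from genes regulated together, since 37 tested members of the class are on the ribosomal protein list. Camera's estimated correlation was 0.541 for ciliate-hit and 0.434 for flatworm-hit genes, a much smaller contrast. The member most abundant in control, beta-tubulin TRINITY_DN34708_c0_g6, chosen after its values were seen, was not called at day 5 (limma, adjusted p = 0.803). It stood at 242 ± 74.3 TPM in control and 210 ± 34.4 TPM at day 5. Fewer ciliates alone would not account for rises, and 3 genes of the class rose: cathepsin L TRINITY_DN2937_c0_g1, actin TRINITY_DN21497_c0_g2 and polyubiquitin TRINITY_DN33189_c2_g3. As for all ciliate-hit genes, the fallers included, their class rests on the Swiss-Prot hit alone, and a rise per ciliate was not tested. The named histone and centrin fallers of the class have animal proteins as their annotation hits. Whether the risers or fallers come from another organism, and whether exposure or time changed the ciliates, stays open and untested.

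Falls made up 76.6% of calls at day 5. A larger share of the total held by the 2 most abundant transcripts may account for the excess but stays open: 54.1% of calls were falls after rescaling without them, yet median-ratio scaling and quantile normalization, which do not single them out, gave 54.9% and 52.4%. Their summed share was 44.4 ± 8.86% in control and 50.8 ± 3.03% at day 5, with overlapping libraries. That exposure lowered many transcripts stays open and cannot be told apart from time, with 0 unexposed libraries placed at day 3 or day 5.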

How the results depend on the processing

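Median-ratio scaling, rescaling without the 2 most abundant transcripts, flatworm hits alone, leaving out both high-median libraries and all scalings of the list tests were chosen after seeing the data. The cause of a changed count was not tested, except that fewer genes or libraries were used where stated. For day 1, day 3, day 5 against control and the 4 groups, quantile normalization gave 74, 869, 1425 and 845 genes and median-ratio scaling 88, 767, 1279 and 775. With fewer genes tested, flatworm hits alone gave 3, 138, 279 and 144, and 4 and 7 for days 3 and 5 against day 1. Limma without an intensity trend gave 266, 501 and 295 for day 3, day 5 and the 4 groups, and leaving out both high-median libraries 161, 488 and 254. Only the 6 libraries compared gave 15, 163 and 481 for days 1, 3 and 5, and the stricter filter 23 for day 1. Apart from the replicate block and single libraries left out, all other gene counts under other settings lay within 1.5 times. Leaving out 1 library at a time gave 15 to 92, 187 to 428 and 275 to 1145 for days 1, 3 and 5 against control, 37 to 78 and 50 to 163 for days 3 and 5 against day 1, 0 to 1 for day 5 against day 3, where the 1 came without day 5 replicate 2, and 272 to 587 for the 4 groups. The first principal component held 19.97% with all tested genes.

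No pairing by replicate number was seen: correlations of deviations between same-numbered libraries ran from -0.148 to 0.150, 1 of 18 pairs was over 0.1, and 3 of 12 libraries correlated best with their own number. With 3 libraries a group this check cannot exclude weak pairing. With the replicate block, day 1 gave 23 genes, days 3 and 5 gave 438 and 780, days 3 and 5 against day 1 gave 52 and 121, the 4 groups 437, days 1 and 5 shared 20 calls, and the ABC transporter list at day 1 and the replication list at day 3 each lost their call (adjusted p = 0.0597).

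No named gene changed sign under any alternative. Of the 68 named results, quantile normalization and the 0.1 pseudocount each ended 2 calls, median-ratio scaling 3, the stricter filter 1, the replicate block 7, rescaling without the 2 most abundant transcripts 12, limma without a trend 26 and the 6-library fits 27; leaving out control replicate 1 ended 28. Of 108 list tests, the estimated correlation ended all 28 calls and fry left 4. These were the vertebrate tissue list at days 3 and 5 (fry, adjusted p = 0.0493 and 0.0197) and the bacterial and oxidative phosphorylation lists at day 5 (fry, adjusted p = 0.0493 for both). No neoblast, replication or ribosomal call was among them. The oxidative phosphorylation list shares 7 members with the vertebrate tissue list, and 7 of its 12 falls at day 5 had bovid hits. Its call is therefore not separate from the bovid-hit transcripts. Neural markers with flatworm hits were called higher than other flatworm-hit genes at day 1 (median 0.005, adjusted p = 0.0405), where the full list leaned lower without a call. Their median lay near control, while that of all flatworm-hit genes was -0.13. Depth is unknown, so no limit of detection can be given.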

Other observations

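The counts and list tests by class of best hit and fry's mixed test were chosen after the results were seen. Cytochrome P450, cholinergic and neural lists had few or no called members. Cytochrome P450 genes, which oxidize foreign compounds, had 0 called among 35 at days 1 and 3 and 1 rise at day 5, with the same numbers adjusted over the list alone. Cholinergic genes, acetylcholinesterase included, had 0 of 32 called at any time, with list medians of -0.04, 0.15 and 0.02. Neural markers had 0 of 125 called at any time, endoplasmic reticulum stress genes 0 of 27, and other phase 1 enzymes 0 of 39, also adjusted over the list alone. Epidermis and secretory markers had 0 of 39 called, with 2 rises at day 3 and 1 rise and 1 fall at day 5 adjusted over the list alone. The phase 2 conjugation list had 2 rises and 3 falls among 36 at day 3 and 1 rise and 5 falls at day 5 (4 and 5, then 2 and 8, adjusted over the list alone). The antioxidant list had 3 rises and 1 fall among 63 at each of these times (3 and 5, then 3 and 2). Neither passed the preset-correlation test as a whole, while fry's mixed test, which asks for change in either direction, gave adjusted p = 1.36e-10 and 8.87e-10 for phase 2 conjugation and 1.44e-07 at both times for antioxidants. That test passed for 13 of 36 lists at day 3 and 16 at day 5, among them the metal list (adjusted p = 5.32e-09 and 8.67e-09). The 18 antioxidant genes with flatworm hits stood lower than other flatworm-hit genes at day 3 (median -0.47, adjusted p = 0.00132) and day 5 (median -0.48, adjusted p = 0.00742), calls lost with an estimated correlation (adjusted p = 0.998). Retrotransposon genes had 1 fall among 259 at day 5 and 0 adjusted over the list alone, and protist, algal and fungal genes 0 of 39.

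In parentheses beside the counts over all genes stand those adjusted over the list alone. At day 5, glycolysis genes had 3 falls among 46 (1 rise, 8 falls), fatty acid genes 1 rise and 2 falls among 49 (1 and 2), muscle markers 3 falls among 65 (8 falls), and the protonephridia list 1 fall among 59 (1 fall). Immune genes had 2 rises and 1 fall among 155 (0), the proteasome and ubiquitin list 2 rises and 6 falls among 233 (2 and 9), and the metal list 2 rises and 6 falls among 59 (3 and 9). The glycine and glutamate list had 2 falls among 51 (1 rise, 5 falls), and the matrix list 3 falls among 63 (1 rise, 9 falls). Apoptosis genes had 2 rises and 4 falls among 173 (2 and 5), the reactive oxygen and MAPK list 1 rise and 1 fall among 173 (0), cilia markers 1 fall among 132 (0), and patterning genes 0 among 45 (0). ABC transporters had 0 among 26 (0). At day 3, apoptosis genes had 3 rises and 4 falls (3 and 6), immune genes 3 rises and 2 falls (3 and 4), the metal list 2 rises and 3 falls (4 and 6), and the proteasome and ubiquitin list 3 falls (4 rises, 10 falls). None of these lists passed the preset-correlation test at day 5, and of them only the patterning list did at day 3. The 68 proteasome and ubiquitin genes with flatworm hits stood lower than other flatworm-hit genes at day 1 (median -0.27, adjusted p = 0.0102), day 3 (median -0.23, adjusted p = 0.00287) and day 5 (median -0.31, adjusted p = 0.0102), with 0, 3 and 6 falls and 0 rises. These calls were lost with an estimated correlation (adjusted p = 0.998). With flatworm hits alone, muscle (adjusted p = 0.0405) and glycolysis genes (adjusted p = 0.00883) also stood lower at day 5, and patterning genes higher (adjusted p = 0.00742). Epidermis and secretory markers stood higher there at day 3 (adjusted p = 0.0405) and retrotransposons at day 1 (adjusted p = 0.00742). An estimated correlation ended each of these as well (adjusted p = 0.998). In 28 of the 80 list tests without a call the median, the mean and the test differed in sign.

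Heat shock genes moved in both directions within 1 list, with 1 rise and 4 falls among 114 at day 5 (3 and 5 adjusted over the list alone) and 3 rises and 3 falls at day 3 (3 and 3). At day 5, HSP70 stood at 52.0 ± 23.9 TPM against 16.3 ± 4.64 in control (TRINITY_DN39397_c1_g1, adjusted p = 0.0409), while a flatworm-hit heat shock protein fell from 319.5 ± 28.7 to 155 ± 14.0 TPM (TRINITY_DN30949_c0_g1, adjusted p = 0.00291) and a mitochondrial 10 kDa heat shock transcript from 6.58 ± 1.23 to 0.0867 ± 0.150 TPM (TRINITY_DN41427_c0_g1, adjusted p = 0.000133). These 2 fallers, and HSP70 at day 5, were chosen after their values were seen. Fry's mixed test gave adjusted p = 0.00751 for the list of 114. A second catalase, also chosen after its values were seen, rose from 24.3 ± 2.82 to 55.5 ± 1.49 TPM (TRINITY_DN36204_c0_g1, adjusted p = 0.00761). Plant-hit genes had 13 rises and 8 falls among 659 at day 5.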
